A study of Homo sapiens with 6 samples.

How the data were processed

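Polyadenylated RNA was sequenced from 786-0 cells labelled SETD2 KO after DMSO, 100 nM decitabine or 300 nM decitabine, with 2 libraries per group and 6 in all. Per the labels, total RNA was taken with a miRNeasy kit and libraries were made by poly-A enrichment. Other libraries named in the series' design are not analysed here.

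The deposited counts are whole numbers of reads per gene for 58381 genes, made by the authors with STAR alignment, SAMtools and featureCounts (1.5.0-p3 per the file headers) on GENCODE v28 gene models, and not normalised. The recorded commands carry no paired-end option and no strand option, so mates were counted separately and antisense reads were not told apart from sense reads. Even numbers made up 70.0% to 74.4% of counts from 1 to 10, the excess that counting both mates gives. The submitters' notes name hg19 and GRCh37, while the coordinates in the count files are those of GRCh38: 56888 genes had the same versioned identifier in GENCODE v29, and all 56888 had the same GRCh38 coordinates there. Coordinates in the text are GRCh38. The deposited log2 matrix holds variance-stabilised log2 values, scaled for library size by the authors. Its function and settings are not stated (DESeq2 is named in the notes), and it held the 37599 genes with a read in any library. Gene names and types were taken from GENCODE v29 for 58261 genes.

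Reads assigned to genes numbered 93342879 and 92793965 with DMSO, 95271726 and 89159112 at 100 nM, and 90475363 and 96646427 at 300 nM. A count of 0 allows a level of up to 3 reads per library, or 0.031 to 0.0336 CPM. Floors and counting intervals (95%, from the exact binomial distribution of reads) cover counting error only, and reads without molecular identifiers, counted for both mates, are not independent molecules. The spread between the 2 libraries of a group exceeded counting error, with a chi-square per gene of 9.0 for DMSO, 24.4 at 100 nM and 44.0 at 300 nM. Log2 CPM correlated across genes between the 2 libraries at 0.9986, 0.9974 and 0.9963, where genes are not independent replicates. The leading principal component of the 500 most variable genes carried 96.4% of their variance and ordered the groups by dose.

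Counts were scaled by TMM and filtered with filterByExpr, which kept 23160 genes. Each comparison (100 nM with DMSO, 300 nM with DMSO, 300 nM with 100 nM) used edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided, at an adjusted p under 0.05, in a single fit of all 6 libraries with group as the factor and 3 residual degrees of freedom (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Levels are CPM with TMM factors, given as mean ± SD over 2 libraries. The biological coefficient of variation was 11.8%. In a test on simulated data with these depths and this spread, the fit recovered 53.7%, 80.6% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold at 100 nM, with 5.5% false calls, and 50.7%, 82.1% and 98.5% at 300 nM, with 8.9% false calls. The changed genes were drawn above a minimum level, so recovery of genes at lower levels was not measured.

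The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The 25 lists cover interferon-stimulated genes, nucleic acid sensing, antigen presentation, NF-kB targets, X-linked cancer-testis genes, autosomal germ-cell genes, imprinted genes, DNA methylation machinery, cytidine analogue handling, lysine 36 methylation of histone H3, S phase, mitosis, p53 targets, DNA repair, apoptosis, hypoxia-inducible factor targets, mesenchymal, epithelial and kidney tubule genes, unfolded protein and ATF4 stress genes, cholesterol synthesis, the respiratory chain, ribosomal proteins, and markers of immune cells and of endothelium and fibroblasts. Lists were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 25 lists. They were tested again with an estimated correlation and with fry, which tests whether a list's genes move one way and compares it with no other genes. On simulated data with 1 list shifted at 300 nM, camera at the preset correlation called that list and 1 list that was not shifted. The named genes were SETD2, DNMT1, DNMT3A, DNMT3B and UHRF1, and protein-coding genes with a mean of at least 1 CPM: the 8 highest fold changes per dose with at least 10 reads in every DMSO library (5 by the same rule for 300 nM against 100 nM) and the 6 lowest. To these came the 6 highest levels among called genes with at most 3 DMSO reads, and up to 4 called members of each list with the smallest adjusted p. The values of 2 of these list members are not reported here. For genes with 0 reads over the DMSO libraries the fold is a lower bound against 3 reads over the group. Because both mates were counted, a bound set in fragments would be lower. Genes of near-identical copies (MAGE, SPANX, VCX, TUBA3, HLA and keratin genes) may share or lose reads, which was not measured. Genes overlapping others on the opposite strand can take their reads. The values of both kinds are uncertain.

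A gene was detected with decitabine and not in DMSO when it had at most 3 reads over the DMSO libraries and at least 10 in each library of the dose. The overlap of the doses was set beside that of independent lists, and the correlation and covariance of their fold changes beside 20 simulations of unchanged groups sharing the DMSO libraries, which are too few to be divided between the doses. Alternatives planned were the RLE size factors, no low-count filter and a minimum of 50 reads in at least 2 libraries, DESeq2 1.42.0, limma on the deposited matrix, the replicate number as a block, only the 2 groups compared, a log2 fold change of at least 1, other detection minimums, thinning to the smallest library, and leaving out each library in turn. Offsets that take out a smooth trend (splines with 4 degrees of freedom) in exon length and GC content per library, and reads halved, were chosen after seeing the data. On simulated data the offsets took a slope of -0.4 per doubling of length to -0.01. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.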

Results

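RNA was sequenced from 786-0 cells, an established human clear cell renal carcinoma line, in which the labels give every library a knockout of SETD2, the histone methyltransferase that places trimethylation on lysine 36 of histone H3. Cells received vehicle (DMSO) or decitabine at 100 nM or 300 nM on each of 3 days, were given fresh medium on day 4 and were harvested on day 5. Decitabine is a deoxycytidine analogue that is built into DNA and traps DNA methyltransferases, so that methylation is lost as cells divide. The 6 libraries analysed here, 2 per group, held between 89159112 and 96646427 reads assigned to genes. By the series title the study asks whether SETD2 loss makes kidney cancer cells sensitive to DNA hypomethylating agents. No library with intact SETD2 is among these samples and other kidney cells named in the design are not analysed here, so the comparisons below are of dose within the knockout cells. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

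The SETD2 transcript (ENSG00000181555.20, GRCh38 chromosome 3, 47016429 to 47163967) was still measured in the knockout cells and fell with dose. Its level was 79.6 ± 2.36 CPM (SD, n = 2) with DMSO, 44.4 ± 6.57 at 100 nM and 19.1 ± 3.74 at 300 nM. The log2 fold change was -0.84 (SE 0.14, adjusted p = 1.0e-04, edgeR quasi-likelihood test) at 100 nM and -2.06 (SE 0.14, adjusted p = 1.5e-09) at 300 nM. Without a library of intact cells, the level cannot check the genotype label. The merged exons of SETD2 span 10.1 kb and its longest transcript has 42.7% GC, against medians of 5.25 kb and 48.2% over 11318 expressed protein-coding genes, and long or AT-rich transcripts were lower with decitabine as a class. With offsets for exon length and GC content, an alternative chosen after seeing the data, its log2 fold change was -0.38 at 100 nM and -0.96 at 300 nM.

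**Figure D1:**
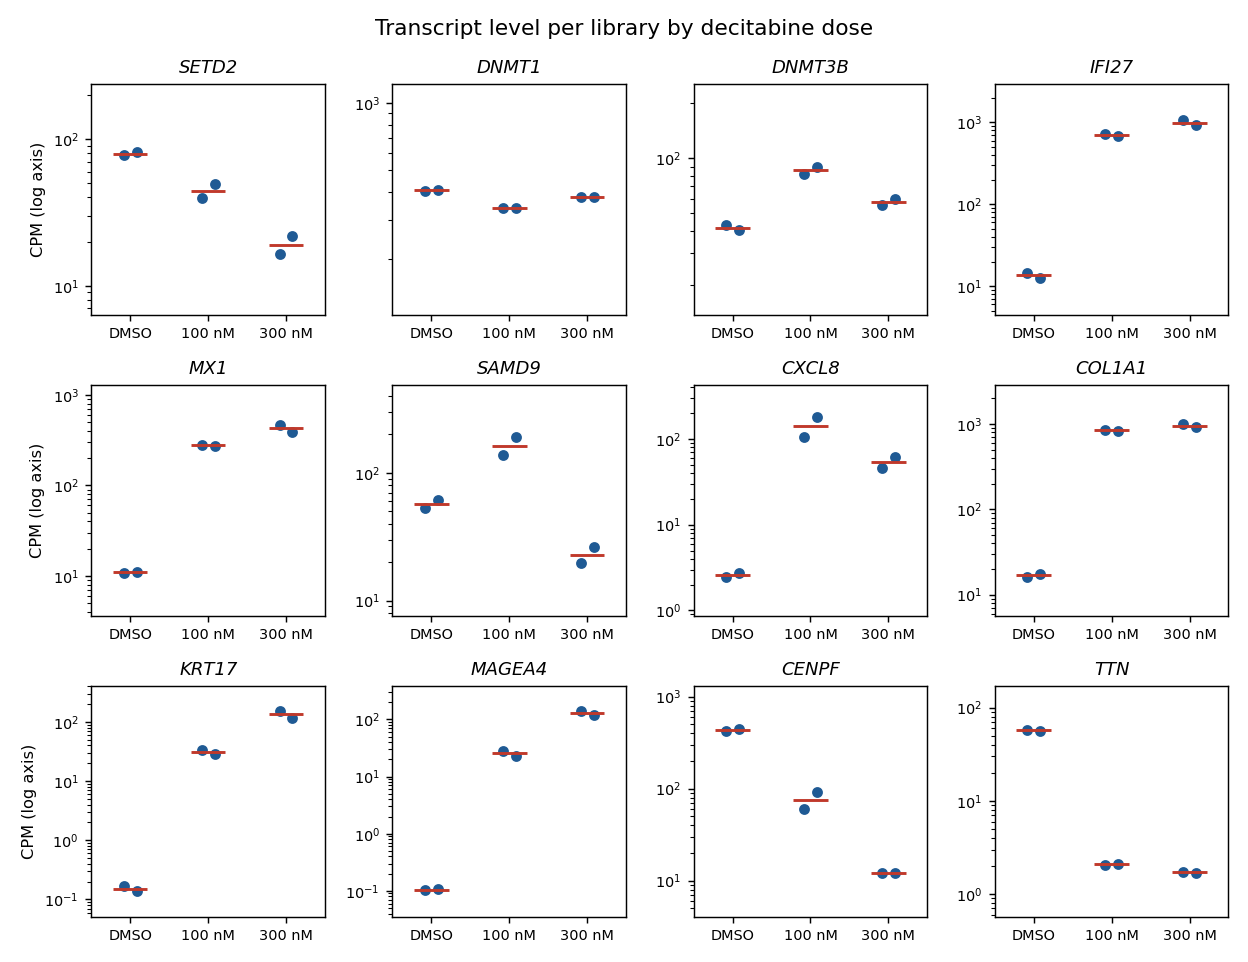
Level of 12 named transcripts in each of the 6 libraries, in CPM (reads per gene scaled to the library) on a log axis, against treatment; blue points are libraries and red lines group means. SETD2 fell from 79.6 to 19.1 CPM, MAGEA4 rose from 0.105 to 128.4 CPM, and SAMD9 was at 57.1, 163.2 and 22.9 CPM with DMSO, 100 nM and 300 nM; its log2 fold change at 300 nM was -1.32, and 0.46 with length and GC offsets.

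At 100 nM, decitabine raised genes of the interferon response, inflammatory cytokines, matrix and keratin genes, and germ-cell genes that were near silent with DMSO, and lowered genes of mitosis. With an estimated correlation the inflammatory and mitosis lists lost their calls (adjusted p = 0.081 for each). Among 23160 tested genes, 5564 were higher and 4331 lower than with DMSO at an adjusted p under 0.05 (edgeR quasi-likelihood test, two-sided). Of these, 3689 rose and 1310 fell at least 2-fold, and 1841 rose against 87 that fell at least 8-fold. Without replicate 1 of 100 nM the number lower was 2883.

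Among protein-coding genes with a mean of at least 1 CPM and at least 10 reads in every DMSO library, the largest rises were MAGEA4, a cancer-testis antigen, COL5A1, a fibrillar collagen chain, and KRT17, a keratin. MAGEA4 (ENSG00000147381.11, chromosome X, 151912509 to 151925170) went from 0.105 ± 0.00166 to 25.7 ± 4.03 CPM, a log2 fold change of 7.91 (SE 0.22, adjusted p = 5.1e-14). COL5A1 rose from 1.03 to 208.5 CPM and KRT17 from 0.152 to 30.9 CPM. SPANXB1, SRGN (the proteoglycan serglycin), MYO1G, ROBO4 and THEMIS2 rose by log2 values of 6.85 to 7.41. Genes with at most 3 reads over both DMSO libraries and the highest levels at 100 nM were CTCFL, the germ-cell paralogue of CTCF, RET, TYROBP, MAGEA11, CSF3 and SH2D2A. CTCFL had 0 DMSO reads and reached 4.99 ± 1.16 CPM, at least 317.7-fold higher when the DMSO group is set to 3 reads. RET had 2 DMSO reads against 749, a ratio of 373.7 (95% counting interval 103.1 to 3091).

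Interferon-stimulated genes rose almost throughout: 60 of 61 tested members were higher, also 60 when adjusted over the list alone, with a median log2 fold change of 2.16 (camera adjusted p = 6.4e-87, and adjusted p = 0.026 with an estimated correlation). IFI27 went from 13.6 ± 1.57 to 698.1 ± 27.3 CPM, and the antiviral genes OAS2, MX2 and MX1 rose by log2 values of 4.86, 5.15 and 4.67. Of the sensors of foreign nucleic acid, their adaptors and the interferon genes, 17 of 25 rose and 2 fell (18 and 2 adjusted over the list alone). Their adjusted p was 0.118 with an estimated correlation. Among those that rose were IRF7 (log2 3.33), DHX58 (3.34) and IFIH1 (2.12). Antigen presentation genes rose in 23 of 29 cases (24, with 1 lower, adjusted over the list alone), led by CD74 (4.33), HLA-F (2.71), PSMB9 (2.61) and TAP1 (2.03), and their adjusted p was 0.072 with an estimated correlation. NF-kB target cytokines and regulators were higher in 31 of 32 members, the same number when adjusted over the list alone, with CXCL8 at log2 5.78, CXCL1 at 4.84 and IL6 at 4.81 (adjusted p = 0.081 with an estimated correlation).

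Of the 25 lists, the 2 germ-cell lists had the highest medians. Of 57 tested X-linked cancer-testis genes 55 rose, also 55 when adjusted over the list alone, and the median log2 fold change was 7.38, or 6.09 with the 28 members that had 0 reads in a group set at their bound (adjusted p = 0.042 with an estimated correlation). MAGEB2 reached 27.3 ± 1.07 CPM from 0.0418, and TKTL1 reached 29.3 CPM from 0.106. Of 47 autosomal germ-cell genes 32 rose and 2 fell (33 and 2 adjusted over the list alone; median 3.15, or 2.66 with members at 0 set at their bound; adjusted p = 0.040 with an estimated correlation), including MAEL, GTSF1 and DAZL. The MAGE, SPANX and VCX genes and the TUBA3 tubulins have near-identical copies, so reads could be split between members and single-gene values are uncertain.

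Structural genes of several cell types rose together. Mesenchymal and matrix genes were higher in 31 of 45 cases and lower in 4 (32 and 4 adjusted over the list alone, adjusted p = 0.048 with an estimated correlation): COL1A1 went from 17.0 to 845.5 CPM and PDGFRB from 1.13 to 27.5. Epithelial junction and keratin genes rose in 34 of 45 and fell in 4 (36 and 4 adjusted over the list alone, adjusted p = 0.049 with an estimated correlation), with KRT81, JUP and CLDN7 among them. Of 14 endothelial and fibroblast markers 10 rose (11 adjusted over the list alone, adjusted p = 0.049 with an estimated correlation), with ENG, a TGF-beta co-receptor, at log2 5.46. Blood and immune cell markers rose in 12 of 17 (12 adjusted over the list alone) and their adjusted p was 0.237 with an estimated correlation. Kidney tubule genes went both ways, with 17 higher and 10 lower of 35 (18 and 10 adjusted over the list alone) and no call as a list (camera adjusted p = 0.327): CDH6, a cadherin, fell from 168.5 to 37.2 CPM, and AQP1, a water channel, rose from 0.420 to 5.33.

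Mitotic genes fell in 44 of 56 cases with 0 higher (47 adjusted over the list alone), with a median log2 fold change of -0.67 (adjusted p = 0.081 with an estimated correlation). The kinetochore gene CENPF went from 435.2 ± 12.7 to 76.1 ± 22.9 CPM, and ASPM, KIF14 and CENPE fell by 2.59, 2.09 and 2.23 on the log2 scale. Genes of homologous recombination, the Fanconi pathway and checkpoints were lower in 27 of 49 and higher in 2 (28 and 3 adjusted over the list alone, adjusted p = 0.309 with an estimated correlation), and S-phase genes were lower in 18 of 50 and higher in 5 (18 and 6 adjusted over the list alone, adjusted p = 0.394 with an estimated correlation). Genes that write, read or erase lysine 36 methylation were lower in 12 of 28 and higher in 3, also 12 and 3 adjusted over the list alone (adjusted p = 0.139 with an estimated correlation). Under the length and GC offsets, 51 mitotic genes were lower and 1 higher, 25 DNA repair genes lower and 8 higher, and 31 S-phase genes lower and 6 higher. CENPE was then at -1.45, and the lysine 36 list was no longer called (camera adjusted p = 0.141).

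Stress and survival genes rose in part. Of 38 p53 targets 18 rose and 3 fell, also 18 and 3 adjusted over the list alone, with GDF15 up from 21.8 to 352.1 CPM (adjusted p = 0.118 with an estimated correlation). Apoptosis genes were 17 higher and 2 lower of 34, the same adjusted over the list alone (adjusted p = 0.153 with an estimated correlation), with BIK, a BCL2-family killer, at log2 4.75. Unfolded protein and ATF4 genes were 19 higher and 6 lower of 35, the same adjusted over the list alone (adjusted p = 0.394 with an estimated correlation), and with offsets the list was not called (camera adjusted p = 0.066). Genes of cytidine analogue handling were 7 higher and 2 lower of 22, the same adjusted over the list alone (adjusted p = 0.283 with an estimated correlation): CDA, the deaminase that inactivates decitabine, rose from 1.38 ± 0.119 to 82.2 ± 6.43 CPM, and SAMHD1 rose by a log2 value of 2.15. The call of this list ended without DMSO replicate 1 (camera adjusted p = 0.091) or 100 nM replicate 2 (0.114), with the replicate block (0.061) and on the deposited matrix (0.059), and with offsets 12 members were higher and 4 lower. DNMT3B, a de novo DNA methyltransferase, rose (log2 1.04, SE 0.11). DNMT1, the maintenance methyltransferase, and its partner UHRF1 fell by 0.26 and 0.31 on the log2 scale (-0.24 and -0.47 with length and GC offsets). Both calls ended without any 1 of the 4 libraries compared, at adjusted p from 0.158 to 0.229 and from 0.062 to 0.166.

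Lists without a call at 100 nM, besides kidney tubule, were DNA methylation machinery (5 higher and 13 lower of 31), imprinted genes (17 and 8 of 30), hypoxia-inducible factor targets (18 and 7 of 41), cholesterol synthesis (15 and 3 of 26), the respiratory chain (6 and 6 of 48) and ribosomal proteins (9 and 4 of 73). Adjusted over the list alone, these were 5 and 14, 17 and 9, 19 and 7, 15 and 3, 5 and 6, and 2 and 3. The missing call of cholesterol synthesis is not firm. It was called without DMSO replicate 2 (camera adjusted p = 0.018), without either 100 nM library (0.014 and 0.005) and without either 300 nM library (0.002). It was also called with no low-count filter (camera adjusted p = 3.5e-04), with the replicate block (0.003), on the deposited matrix (0.009), with only the 2 groups compared (0.017) and with the offsets (0.016). Hypoxia targets were called without DMSO replicate 1 (0.049) or 100 nM replicate 1 (0.017) and with no low-count filter (0.041). Imprinted genes were called without 100 nM replicate 1 (0.041), with no low-count filter (0.026) and on the deposited matrix (0.029). The median, mean and test of the DNA methylation, respiratory chain and ribosomal protein lists did not share a sign.

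Among protein-coding genes with a mean of at least 1 CPM over all libraries, 5 of the 6 deepest falls at 100 nM were in striated muscle genes. MYH7, the cardiac slow myosin heavy chain (chromosome 14, 23412738 to 23435718), had 3266 reads over the DMSO libraries and 2 at 100 nM, a ratio of 1636 (95% counting interval 452.7 to 13520). MYL2, ACTC1, TTN and ACTA1 were the others, and VAV3, a guanine nucleotide exchange factor, fell from 7.23 to 0.342 CPM. TTN went from 56.9 ± 1.59 to 2.08 ± 0.0437 CPM. In a list of 42 heart genes chosen after some of these values were seen, 24 of 40 tested were lower at both doses and 4 higher. Those 24, selected as lower, summed to 122 and 112 CPM in the DMSO libraries, and to 8.02 to 9.36 CPM in the decitabine libraries. Over all 40 tested, the median log2 fold change at 300 nM was -1.84, with 24 lower and 8 higher.

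At 300 nM germ-cell and keratin genes were far above their DMSO levels, and more genes fell than at 100 nM. The test called 8060 genes higher and 7203 lower than with DMSO, of which 4970 and 4639 changed at least 2-fold. MAGEA4 reached 128.4 ± 13.2 CPM (log2 fold change 10.23, SE 0.22), KRT17 134.7 ± 28.2, KRT7 110.9 ± 16.6 and IGFBP4, an insulin-like growth factor binding protein, 105.3 ± 21.0. FBXO2, MYO1G, SPANXB1 and FBLIM1 rose by log2 values of 8.28 to 8.69. From at most 3 DMSO reads, MAGEB1, VCX3A, VCX2, HDGFL1, CTCFL and CXorf67 reached 9.74 to 15.8 CPM. VCX3A, with 0 DMSO reads, was at least 955.8-fold higher when the DMSO group is set to 3 reads.

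All 57 tested cancer-testis genes rose at 300 nM, also adjusted over the list alone (median 8.51, or 7.16 with members at 0 set at their bound; adjusted p = 0.049 with an estimated correlation). Of the autosomal germ-cell genes 38 of 47 rose and 2 fell (38 and 3 adjusted over the list alone; adjusted p = 0.049 with an estimated correlation). Epithelial genes rose in 38 of 45 and fell in 5, mesenchymal genes rose in 31 and fell in 6 of 45, and endothelial and fibroblast markers rose in 11 of 14, each with adjusted p = 0.065 with an estimated correlation (38 and 5, 32 and 6, and 12 adjusted over the list alone). NF-kB targets were 30 higher and 2 lower of 32 and antigen presentation genes 24 higher and 1 lower of 29 (30 and 2, and 25 and 1, adjusted over the list alone; adjusted p = 0.169 and 0.141 with an estimated correlation). Nucleic acid sensing genes were 16 higher and 6 lower of 25, immune cell markers 15 higher of 17, and p53 targets 23 higher and 9 lower of 38. The numbers were the same in each case adjusted over the list alone. Their adjusted p was 0.336, 0.278 and 0.252 with an estimated correlation, and with offsets the immune cell list was not called (camera adjusted p = 0.081).

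Interferon-stimulated genes were 45 higher and 8 lower of 61 at 300 nM, also when adjusted over the list alone, with a median of 1.54 (adjusted p = 0.049 with an estimated correlation). IFI27 was at 988.7 ± 100.4 CPM and MX1 at 430.1 ± 52.2. With length and GC offsets 57 were higher and 2 lower.

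Mitotic genes at 300 nM were lower in 37 of 56 and higher in 5 (37 and 6 adjusted over the list alone), with CENPF at 12.1 ± 0.0825 CPM and ASPM at 4.56 ± 0.229 (adjusted p = 0.141 with an estimated correlation). DNA repair genes were lower in 32 of 49 and higher in 5, the same adjusted over the list alone: BRCA2 fell from 28.1 to 1.04 CPM, ATM from 58.4 to 4.51 and ATR from 60.3 to 7.48 (adjusted p = 0.278 with an estimated correlation). Among protein-coding genes with a mean of at least 1 CPM, the 6 deepest falls were in MYH7, MYL2, IGIP, ASPM, CENPF and VPS13A. Lysine 36 methylation genes were lower in 15 of 28 and higher in 8, and ribosomal protein genes 44 higher and 11 lower of 73, the same adjusted over the list alone (adjusted p = 0.169 and 0.692 with an estimated correlation). With length and GC offsets neither of these 2 lists was called (camera adjusted p = 0.181 and 0.338), 44 mitotic genes were lower and 7 higher, and 28 DNA repair genes lower and 12 higher. The DNA repair median went from -0.73 to -0.31, and the log2 fold changes of BRCA2, ATM and ATR were -2.63, -1.61 and -1.36. VPS13A went from -5.17 to -2.81 and ASPM from -5.34 to -3.40. MSH6, PLOD2, CMPK1, LBR, STARD4 and NDUFA5 were called lower and lay above 0 with the offsets, and DNMT3B, called higher (log2 0.47), was at 0.01. DNMT1 (log2 -0.10, edgeR adjusted p = 0.357) and UHRF1 (-0.20, 0.082) were not called at 300 nM. With the offsets both were called, at -0.18 and -0.63. DNMT3A was at -0.33 (edgeR adjusted p = 0.061) at 100 nM and -0.32 (0.048) at 300 nM. Its call at 300 nM did not hold with the offsets (edgeR adjusted p = 0.066), nor when any 1 of the 6 libraries was left out. With a library left out, its log2 fold change at 300 nM lay from -0.34 to -0.31. At 100 nM DNMT3A was called without either 300 nM library (log2 -0.32). Lysine 36 methylation also lost its call with a minimum of 50 reads (camera adjusted p = 0.056) and on the deposited matrix (0.059), and ribosomal proteins with that minimum (0.056). The other lists had no call at 300 nM. With offsets, apoptosis (camera adjusted p = 0.008), cytidine analogue (0.002) and imprinted genes (0.012) were called, and imprinted (0.043) and respiratory chain genes (0.029) were with no low-count filter, the former also on the deposited matrix (0.039). For S-phase and cholesterol synthesis genes the median was above 0 while the mean and test were below.

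Fold changes followed the annotated exon length and GC content of expressed protein-coding genes, more steeply at the higher dose. Over 11318 expressed protein-coding genes, the median log2 fold change at 300 nM ran from 0.49 in the sixth with the shortest exons (0.38 to 2.81 kb) to -0.74 in that with the longest (9.03 to 118.98 kb). At 100 nM it ran from 0.15 to -0.37. Log2 fold change at 300 nM also rose by 0.801 for each 10 points of GC content at a given length. Length alone explained 11.5% of its variance across these genes, and length with GC 32.4%. Between the 2 libraries of 300 nM the same medians ran from 0.14 to -0.14, and between the 2 DMSO libraries from 0 to -0.05. Median exon length and GC content, untested against other genes, were 4.32 kb and 42.9% for mitotic, 6.07 kb and 43.4% for DNA repair, 6.66 kb and 48.4% for lysine 36 methylation and 4.77 kb and 44.4% for interferon-stimulated genes.

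**Figure D2:**
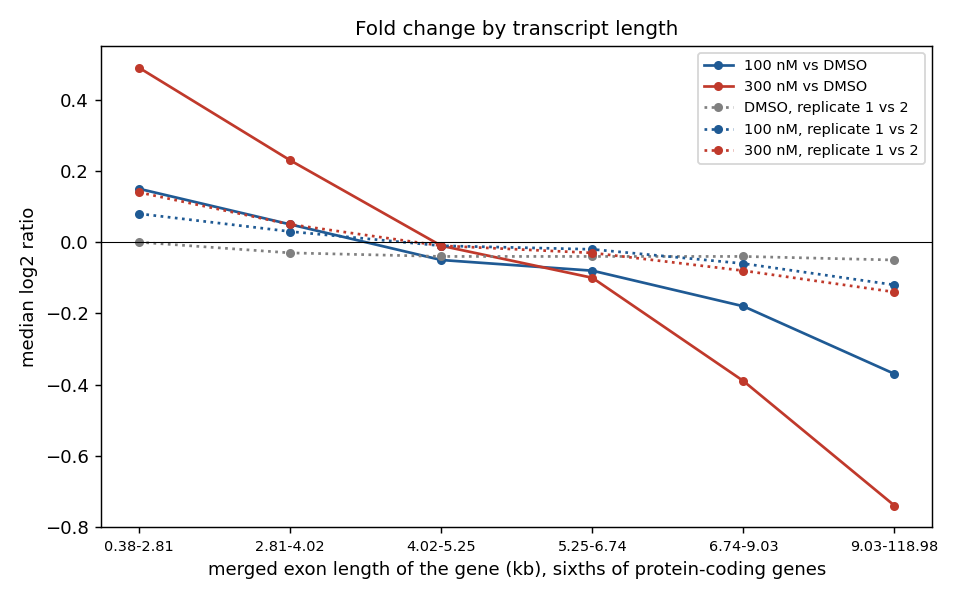
Median log2 ratio (vertical axis) of expressed protein-coding genes in 6 equal groups of merged exon length in kb (horizontal axis); solid lines compare each dose with DMSO and dotted lines compare the 2 replicates of a group. The 300 nM line runs from 0.49 to -0.74, and the 300 nM replicate line from 0.14 to -0.14.

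The doses changed largely overlapping sets of genes. Of the genes higher at 100 nM, 5030 (90.4%) were also higher at 300 nM, and of those lower 3797 (87.7%) were also lower. Independent lists would share 1936 and 1347. The log2 fold changes of both doses correlated across genes at 0.91, against 0.50 in 20 simulations of unchanged groups sharing the DMSO libraries, with a covariance of 4.096 against 0.081. Genes are not independent replicates. In these simulations, which share the DMSO libraries at the fitted spread, the mean overlap was 0 for higher and 0 for lower genes. No gene was changed in them, so an overlap near 0 follows. It does not measure what the shared DMSO libraries add to the overlap among changed genes. A shift common to both DMSO libraries beyond the fitted spread was not simulated, and part of the excess may come from it.

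**Figure D3:**
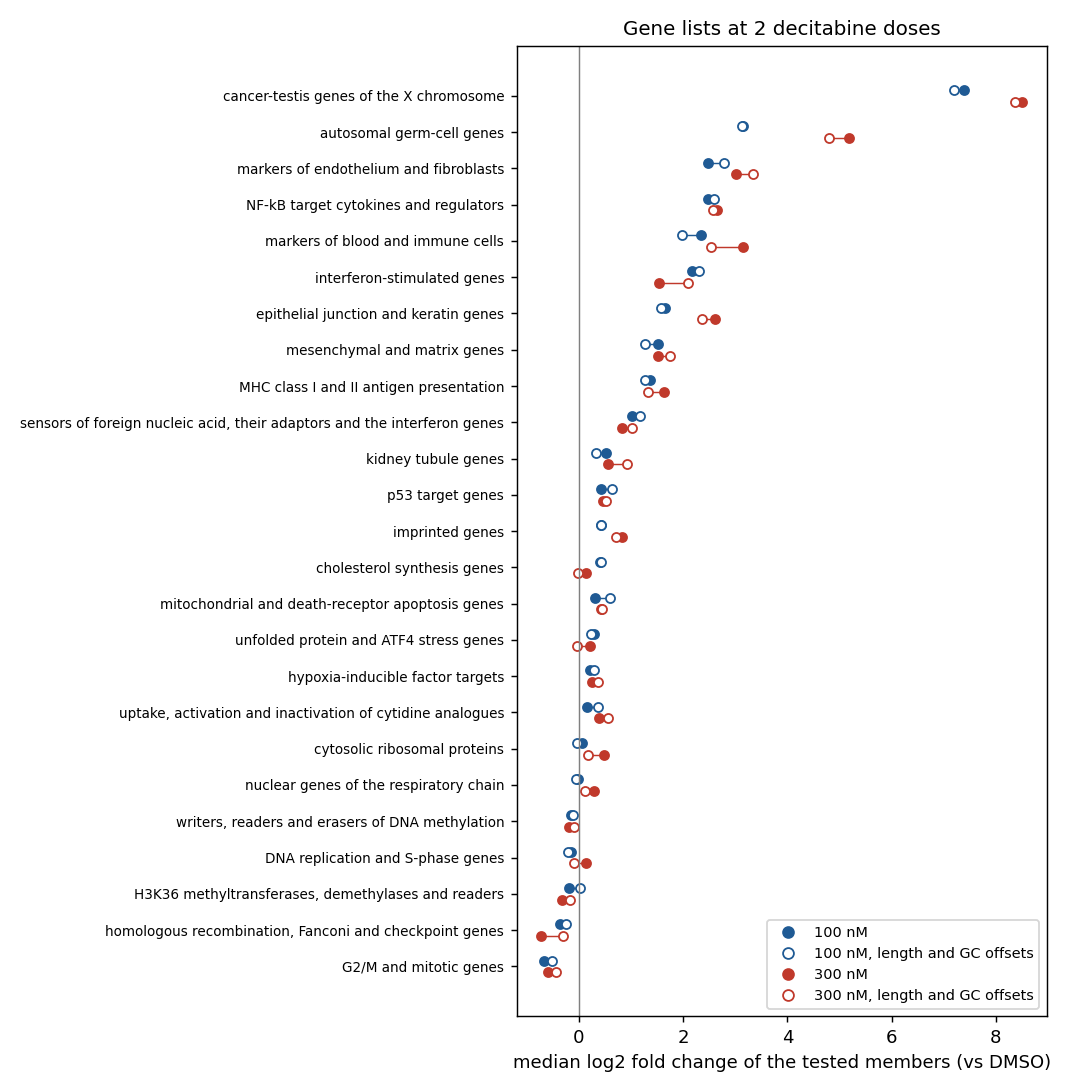
Median log2 fold change against DMSO (horizontal axis) of the tested members of 25 gene lists (vertical axis) at 100 nM in blue and 300 nM in red; open points are the medians with length and GC offsets. Cancer-testis genes had medians of 7.38 and 8.51, and mitotic genes -0.67 and -0.60.

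Against 100 nM, more germ-cell and epithelial genes were higher than lower at 300 nM, and more interferon-stimulated genes were lower than higher. With an estimated correlation none of these lists held its call (adjusted p = 0.116 for cancer-testis, 0.080 for autosomal germ-cell, 0.149 for epithelial and 0.283 for interferon-stimulated genes). The test called 4623 genes higher and 5431 lower, 1387 and 2499 of them at least 2-fold, and without replicate 2 of 100 nM the number higher was 2896. The excess of lower genes turned under other scalings, with 5396 higher and 4949 lower by RLE size factors, 5139 and 4694 by DESeq2 and 4829 and 4316 on the deposited matrix. Under the same limits on level and DMSO reads, the largest rises were NPPB, a natriuretic peptide (0.405 to 12.4 CPM), CLDN6, a tight junction protein (1.46 to 35.5), KRT7 (8.63 to 110.9), EDN2 and NEURL1. The deepest falls among protein-coding genes with a mean of at least 1 CPM were in IGIP, ZMAT1, ELN, ZNF624, BRCA2 and EEA1, with elastin (ELN) going from 22.9 ± 3.47 to 1.95 ± 0.281 CPM. Under the offsets BRCA2 went from -3.31 to -2.04 and EEA1 from -3.18 to -1.84. Cancer-testis genes were higher in 44 of 57, germ-cell genes in 30 of 47 with 2 lower, and epithelial genes in 29 of 45 with 5 lower (46, 30 with 2, and 32 with 6 adjusted over the list alone). DNMT3B was lower at 300 nM than at 100 nM (log2 -0.57, SE 0.11).

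Interferon-stimulated genes were lower at 300 nM than at 100 nM in 30 of 61 cases and higher in 12 (33 and 14 adjusted over the list alone), with a median of -0.39 (adjusted p = 0.283 with an estimated correlation). SAMD9 went from 163.2 ± 37.0 to 22.9 ± 4.55 CPM and SAMD9L, DDX60 and IFI44L fell to between 7.86 and 20.2 CPM. Under the offsets 34 members were lower and 7 higher, and the log2 fold change of SAMD9 went from -2.83 to -1.72, of DDX60 from -2.42 to -1.57 and of IFI44L to -1.41. Cholesterol synthesis genes were lower in 14 of 26 and higher in 1 (14 and 4 adjusted over the list alone, adjusted p = 0.462 with an estimated correlation), with INSIG1 falling from 304.8 to 133.5 CPM and HMGCS1 from 173.4 to 69.2 (log2 -0.67 with length and GC offsets, -1.32 without). Mitotic genes were lower in 27 of 56 and higher in 16, and DNA repair genes lower in 26 of 49 and higher in 6 (28 and 17, and 26 and 8, adjusted over the list alone; adjusted p = 0.462 for both with an estimated correlation). With offsets the counts were 23 lower and 21 higher for mitotic and 19 and 10 for DNA repair genes, and the mitotic list was not called (camera adjusted p = 0.132), nor without either 300 nM library (0.070 and 0.064), with no low-count filter (0.071), with the replicate block (0.061) or on the deposited matrix (0.090). Mesenchymal genes were higher in 17 of 45 and lower in 9, respiratory chain genes higher in 23 of 48 and lower in 4, and ribosomal protein genes higher in 41 of 73 and lower in 4 (20 and 9, 25 and 4, and 42 and 5 adjusted over the list alone). Their adjusted p was 0.462, 0.608 and 0.582 with an estimated correlation, and without 100 nM replicate 1 the mesenchymal list was not called (camera adjusted p = 0.117). Of the 25 lists 10 were called with the preset correlation. With an estimated correlation the lowest adjusted p was 0.080, and 4 lists had an unadjusted p under 0.05. With the offsets, imprinted (camera adjusted p = 0.012) and nucleic acid sensing genes (0.015) were also called. Immune cell markers were called with no low-count filter (camera adjusted p = 0.031) and on the deposited matrix (0.008).

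Many genes were detected with decitabine and not in DMSO. By the rule of at most 3 reads over the DMSO libraries and at least 10 in every library of the dose, 642 genes qualified at 100 nM and 1072 at 300 nM, 546 of them at both. The rule with the groups exchanged gave 50 and 265. With a library left out fewer libraries must meet the rule, so the numbers cannot fall by construction. Without DMSO replicate 1 or 2 the number at 100 nM was 1058 or 1044. The exchanged rule was run without DMSO replicate 1, DMSO replicate 2, replicate 1 of the dose or replicate 2 of the dose. It gave 173, 162, 207 and 198 at 100 nM, and 492, 489, 514 and 757 at 300 nM. Of the 1072 genes, 644 were protein coding, 122 were pseudogenes and 37 were members of the cancer-testis list. Because both mates of a pair were counted, 10 reads can come from as few as 5 fragments.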

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

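The length and GC offsets and the halved reads were chosen after seeing the data, and the other alternatives were planned. Over the alternatives other than the fold threshold and the left-out libraries, each count of changed genes stayed within 1.5 times its value, and no scaling moved the median log2 fold change of all genes by more than 0.1. SETD2 at 300 nM against DMSO was -2.06, from -2.07 to -0.96 over the alternatives and from -2.27 to -1.87 without each library in turn. Of 344 values of named genes, 344 kept direction and call with reads halved, 341 with DESeq2 and 317 with the offsets, under which 13 lost and 2 gained a call and 12 reversed. Of 75 list results the offsets left 63 on their side of the threshold, ended 6 calls and added 6.

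A log2 fold change of at least 1 left 3689 higher and 1310 lower genes at 100 nM, 4970 and 4639 at 300 nM, 1387 and 2499 between the doses, and 1184 lower at both doses, since it is a stricter rule. With an estimated correlation in camera, 6, 3 and 0 lists were called at 100 nM, at 300 nM and between the doses, where 10, 8 and 4 had an unadjusted p under 0.05. Fry, which compares a list with no other genes, called 23 at 100 nM, 23 at 300 nM and 14 between the doses. A stricter detection rule gave fewer genes by construction: with at least 20 reads in each library 340 at 100 nM and 631 at 300 nM, and with 0 DMSO reads 372 and 689. Without each library in turn, where a lone library is assumed to vary like the other groups, genes lower at 100 nM numbered 2883 (without 100 nM replicate 1) to 5036, genes higher at 300 nM than at 100 nM 2896 (without 100 nM replicate 2) to 4901, and genes detected at 100 nM 939 to 1058 (without DMSO replicate 1), the last because fewer libraries must meet the rule. The cause was not tested for the other counts.

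With length and GC offsets these genes, called lower, had log2 values not below 0. At 100 nM NDUFA5 was at 0.23. At 300 nM NDUFA5 was at 0.57, CMPK1 at 0.23, MSH6 at 0.11, PLOD2 at 0.53, LBR at 0.14 and STARD4 at 0.10. At 300 nM against 100 nM NDUFA5 was at 0.34, CMPK1 at 0.05, MSH6 at 0.01, PLOD2 at 0.21 and SEL1L at 0. The offsets take out the length and GC trend by design, and its part in each of these falls was not tested.

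The replicate numbers are not said to pair libraries. With the replicate number as a block, 6179 genes were higher and 5140 lower at 100 nM, 8344 and 7521 at 300 nM, and 5299 and 6044 between the doses. Differences between replicates 1 and 2 correlated across genes at 0.26 (DMSO with 100 nM), 0.42 (DMSO with 300 nM) and 0.6 (between the doses), and at -0.06, 0.07 and 0.29 after the offsets. With 2 numbers, pairing is not shown. Depth limits the genes under 0.031 to 0.0336 CPM, where 3 reads cannot be told from 0.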

Other observations

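Of the tests below, those on genomic span and on GC content alone were written before their coefficients were seen, though the trend itself had been seen, and the other tests, the heart gene list and the gene families were chosen after the result was seen.

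Histone genes, read here from polyadenylated RNA, were more often higher than lower with decitabine: 18 of 44 tested were higher and 2 lower at 100 nM, and 24 higher and 1 lower at 300 nM (edgeR). Keratins rose in 21 of 29 cases with 2 lower at 100 nM, and in 27 with 0 lower at 300 nM, with medians of 2.97 and 3.63. With length and GC offsets 1 keratin was lower at 300 nM. Serpins, a family of protease inhibitors, were higher in 14 and then 17 of 21. Metallothioneins, which bind metal ions, were higher in 5 and then 7 of 8, and with offsets 1 of the 8 was lower at each dose. Similar copies within these families may share reads, which was not measured.

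Of the 13 mRNAs of the mitochondrial genome 10 fell at 100 nM and 12 at 300 nM, with 1 higher at 300 nM and medians of -0.42 and -0.71. Mitochondrial genes took 4.23% and 4.28% of reads with DMSO, 3.42% and 3.56% at 100 nM, and 2.55% and 3.08% at 300 nM. Zinc-finger genes named ZNF were lower in 150 and higher in 60 of 473 at 100 nM, and lower in 275 and higher in 92 at 300 nM. With offsets these numbers were 119 and 96, then 206 and 108. Clustered protocadherins were higher in 12 and lower in 1 of 31 at 100 nM, and higher in 11 and lower in 7 at 300 nM. Of 10 annotated endogenous retrovirus genes, 2 were higher and 3 lower at 100 nM, and 3 and 5 at 300 nM. Over all 23160 tested genes, 5564 were higher and 4331 lower at 100 nM, and 8060 and 7203 at 300 nM. The 10 were taken by gene symbol, and repeat elements were not counted.

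Long, AT-rich transcripts were lower and short, GC-rich ones higher at 300 nM, with a slope of -0.569 log2 units per doubling of exon length over 11318 coding genes. GC content alone is argued against, since the coefficient of length given GC was -0.351 (SE 0.013). A difference in RNA integrity or fragment length between libraries stays open. The 2 libraries of 300 nM differed by -0.081 per doubling, where DMSO libraries differed by -0.017. Given GC content the 300 nM difference was only -0.024, with 0.208 for each 10 points of GC. Length alone explained 7.1% of the variance between these 2 libraries, and length with GC 51.1%. The raw slope passed the size set for this cause and the slope given GC did not, so this comparison cannot decide. Given exon length and GC, the coefficient of genomic span was -0.041 (SE 0.009). This argues against a block to transcription through long genes of the predicted size, which was a steeper fall by many SE. A weaker block stays open, since the value was too close to the bound of -0.05 to decide. Dose and library quality are confounded between groups, and no RNA integrity value is given.

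Many heart-muscle transcripts were lower with decitabine: of 42 listed, 40 were tested and 24 were lower at both doses, with TTN at 56.9 CPM, MYH7 at 17.2 and MYL2 at 4.83 in the DMSO group. A single source of heart RNA shared by both DMSO libraries is argued against by unequal ratios between them, as MYL7 had a ratio of 4.62, CMYA5 0.352 and TTN 1.04: the chi-square of the 24 ratios, halved for mates, was 439, against a median of 45.8 and a highest of 130 in 10000 sets of other genes with like DMSO reads. The length and GC trend is argued against as the whole cause, since the offsets moved the median no nearer to 0. Over all 40 tested genes, of which 8 were higher at 300 nM, the median was -1.84 and with offsets -1.92 (95% bootstrap interval -3.35 to -0.91). The interval treats genes as independent, and the list was chosen after some values were seen, so the interval itself adds no support. The sets of other genes came from the same 2 libraries. The unequal ratios therefore argue equally against loss of muscle genes that the cells expressed evenly in both. Different sources of muscle RNA in each DMSO library were not tested. For these 24 genes they cannot be told apart from loss of muscle genes that the cells expressed unevenly, because nothing in the design separates these causes. ANKRD1, CKM, CRYAB and SLN, also on the list, were higher at both doses, and the list was not compared with kidney cells.

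Interferon-stimulated genes were more often lower than higher at 300 nM against 100 nM, with a median of -0.39 over 61 members. The list had no call with an estimated correlation (camera adjusted p = 0.283). With length and GC offsets the median was -0.24 (95% bootstrap interval -0.46 to -0.09, 2000 resamples), with 34 lower and 7 higher, against 30 and 12 without. Members with exons longer than 4.77 kb had a median of -0.70 and the others -0.06, and with offsets -0.33 and -0.21. The length and GC trend is argued against as the whole cause, since this interval lies below 0, though it treats genes as independent. The trend may account for part of the fall, and a weaker response at the higher dose stays open, untested.

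A hypothesis was that genes detected at 300 nM and not in DMSO are X-linked more often than the cancer-testis list explains. Of 1056 such genes on chromosomes 1 to 22 and X, 99 (9.4%) were X-linked, against 1469 of 31008 (4.7%) genes with at most 3 DMSO reads (odds ratio 2.16, 95% interval 1.72 to 2.68, Fisher's exact test, two-sided, p = 1.2e-10). Without the list, 62 of 1019 (6.1%) were X-linked against 4.6% (odds ratio 1.37, interval 1.03 to 1.78, Fisher's exact test, p = 0.022), so the X share stayed above this background. The background took genes of every type, also those with no read in any library, and was not matched to the detected genes. This comparison therefore cannot decide whether an X-linked excess lies beyond the list. Other cancer-testis genes missing from the list, gene clusters and reads shared between copies were not tested.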
